A study of Manihot esculenta with 42 samples.

How the data were processed

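Each of 42 RNA samples of cassava, in 14 groups of 3, was hybridised to a single-colour Agilent array with 62976 spots, of which 61657 were not controls, for 59079 probes. Per the file headers, the arrays were read with Feature Extraction 10.7.3.1, which subtracts a background (method code 7) with spatial and multiplicative detrending and surrogates for dim spots, and the label is given as Cy3. The processed signal in those files is an intensity per the file headers, corrected within the array and not scaled between arrays. The table of values deposited beside them is in log2, with each array's 75th percentile at 0, and was recognised by setting each column against the same array's processed signal (Pearson's r at least 0.999961, column medians -3.40 to -2.99). Its probes are not centred across arrays, and how the authors computed it is not stated in the labels. Arrays had 0 saturated spots, at most 7 spots with an outlier mark among those not controls, and 15.9 to 29.9% of the signal in their 100 brightest probes. The lowest correlation between replicates was 0.966.

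Values were log2 of the processed signal minus the array's 75th percentile, averaged over the spots of a probe, without controls and spots with outlier marks. A probe was tested where it was well above background on all 3 arrays of at least 1 group, which left 41512 probes of 28977 genes. The descriptions of the array file name a gene after its closest Arabidopsis match, and 38191 probes have an informative one. A gene with several probes is given by the one with the highest mean. The reference table of locus tags and accessions matched 0 of the probes' accessions, so no coordinates are given.

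Each of 18 comparisons and 1 interaction was a contrast in limma 3.58.1 (R 4.3.3, with data.table at 1.17.8) with a mean per group over all 42 arrays, 28 residual degrees of freedom and moderated variances. A probe passed with a Benjamini-Hochberg adjusted p under 0.05, two-sided, and a difference of at least 2-fold. Adjustment was over all probes of a comparison. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Comparisons, the 24 gene lists, thresholds, the rule for named genes and the alternatives, except those called added, were chosen before the data were examined.

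The 24 lists were patterns on the descriptions, and 22 held at least 3 tested genes: starch synthesis, starch breakdown, sucrose, auxin, cytokinin, gibberellin, jasmonate, abscisic acid, ethylene, brassinosteroid, lignin, xylem and secondary wall, wall loosening, cell division, KNOX with BELL and MADS, photosynthesis, phloem, latex, storage root proteins, heat shock, wounding and defence, and ribosomal proteins. Each was tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. With the estimated correlation, 2 of 49 calls of these lists held: starch synthesis for storage parenchyma against pre-tuberous root at week 8, and photosynthesis for leaves against fibrous root. It gave the highest adjusted p of all settings tried for a list in 48 of the 49 calls. Of 10 lists added later, 1 of 32 calls held.

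Named genes were, in the comparisons of storage parenchyma with pre-tuberous root and storage cortex, the 8 largest rises and 8 largest falls past both thresholds whose groups did not overlap and whose annotation was informative, in the others the 3 largest of each, and up to 4 members of each list with the smallest adjusted p. Of these, the text names a part. Descriptions that held a locus number alone were counted as no annotation, which was decided after the named genes were first seen. Genes given for the interaction are ones the rule named for week 8, so they were chosen after their values there were seen. With 3 against 3, chance gives groups that do not overlap for 10% of genes.

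Replicate numbers were checked for pairing by correlating the deviations of same-numbered samples from their group means, with a pair counted where every r was over 0.1. The pairing comes from these data, not from the labels. It held for storage cortex with pre-tuberous root at week 12 (r = 0.181, 0.11 and 0.165), at week 8 for intermediate parenchyma (0.152, 0.133 and 0.25) and intermediate cortex (0.191, 0.125 and 0.137) with pre-tuberous root, for storage parenchyma with storage cortex (0.435, 0.438 and 0.355), and for intermediate parenchyma with intermediate cortex (0.218, 0.258 and 0.327).

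The arrays lay on 6 slides, slides 1 to 3 scanned on day 1 and slides 4 to 6 on day 2. Alternatives were quantile normalization, median centring, normexp background correction (offset 50) on the mean and background signals, the deposited table, no filter on dim probes, a filter on the compared groups, no fold threshold, adjusted p under 0.01, 1 probe per gene, the compared arrays alone, a trended robust prior, the replicate block, slide as a fixed or a random block (consensus correlation 0.0174), the arrays of 1 slide alone, leaving out each replicate, an estimated correlation, and all probes of a list. Added after the data were seen were scaling on the mean of 7 spike-in probes, root arrays alone, storage cortex of week 12 by replicate 1 alone, list tests under the other scalings and blocks, 10 more lists, and storage against intermediate parenchyma.

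Data of this size were simulated with 200 genes changed per comparison. In 4 comparisons the fit recovered 6.5 to 10.5% of 1.5-fold, 24.2 to 50% of 2-fold and 76.3 to 82.4% of 4-fold changes. It called 17 unchanged and 353 changed genes (4.6% false). Since 22.1 to 39.3% of probes passed in the data, these rates need not hold. On 6000 simulated genes of 1 comparison, camera found a shift of 0.5 in 40 genes in 100% of 100 draws and called 2% of unshifted lists. Correlated lists were not simulated.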

Results

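Transcript levels were measured during tuberous root development in field-grown cassava (Manihot esculenta) of the cultivar KU50, on 42 arrays each hybridised with RNA of a single sample. The 14 groups of 3 arrays were fibrous root at week 4, pre-tuberous root at weeks 8 and 12, cortex and parenchyma of intermediate and of storage root at weeks 8 and 12, and leaves at weeks 4, 8 and 12 after planting. Per the labels, a root's diameter set its class: under 2 mm for fibrous and pre-tuberous, 2 to 5 mm for intermediate, and over 5 mm for storage root. Between 54.8 and 63.0% of the probes on an array were well above background, and the 75th percentile of the processed signal lay between 244 and 679. The 3 arrays per group limit the precision. The replicates are described as independent biological samples without saying whether each was a plant or a pool, so each p-value measures only the spread between these samples. A gene's value below is its log2 difference ± SE (n = 3 per group), positive where the first-named group was higher.

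The first principal component took 57.5% of the variance of all 42 arrays, and the second, with 15.2%, set the parenchyma samples of week 12 between 189 and 208 apart from the other roots. The 3 storage cortex samples of week 12 did not lie together on it: replicate 1 lay at -36, replicate 2 at 43.7 and replicate 3 at 56.3, towards the parenchyma.

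**Figure D1:**
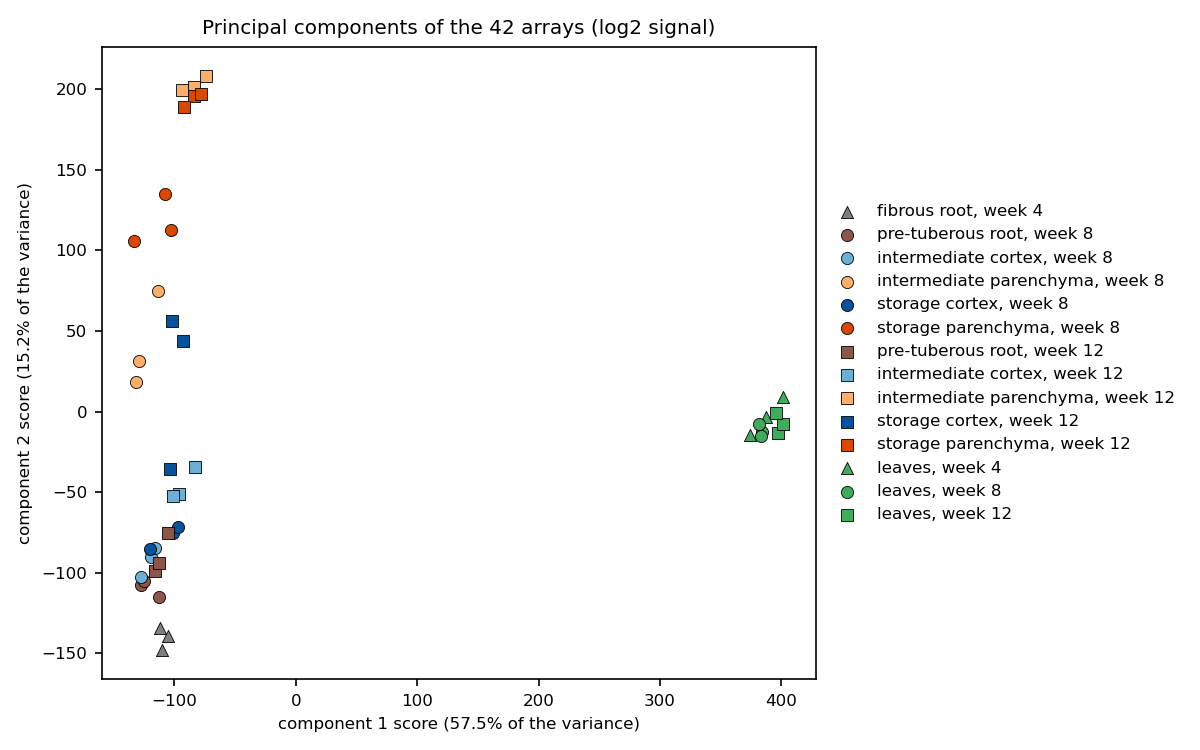
Scores of the 42 arrays on principal components 1 (horizontal, 57.5% of variance) and 2 (vertical, 15.2%), in units of scaled log2 intensity, 1 point per array, coloured by group (n = 3 each). Parenchyma of week 12 lies between 189 and 208 on component 2.

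Storage parenchyma was set against pre-tuberous root at week 8 to ask which genes differ between a thin root and the starch-storing tissue. The labels name no tissue for pre-tuberous root. A contrast of cortex or parenchyma with it, here and below, therefore cannot tell the tissue taken from the stage of thickening. In the list of starch synthesis, 30 of 42 genes rose, 1 fell and 11 did not pass (30 and 1 adjusted over the list alone, median 1.22, adjusted p = 2.19e-10, adjusted p = 0.0421 with an estimated correlation). In the list of wounding and defence, 11 of 69 genes rose, 30 fell and 28 did not pass (11 and 30 over the list alone, median -0.53, adjusted p = 0.00552, adjusted p = 0.61 with an estimated correlation). Among hormone genes, the enzyme of a late step of brassinosteroid synthesis was among the largest rises, while a pair of enzymes that inactivate gibberellin fell to background. A 4-coumarate:CoA ligase of lignin precursors, a MADS gene of the root and a sieve-tube lectin were also lower in the storage tissue.

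Of 41512 probes, 6008 were higher and 5937 lower, from 4315 and 4498 genes. The largest rises included brassinosteroid-6-oxidase 1 (cassava4.1_008216m, at least 266-fold higher), a RING/U-box protein (cassava4.1_025237m, at least 102-fold higher) and a polyketide cyclase (cassava4.1_017693m, 7.70 ± 0.67). The largest falls included flowering promoting factor 1 (cassava4.1_027588m, at least 497-fold lower), a thioredoxin (cassava4.1_033785m, at least 174-fold lower) and an inhibitor of invertase or pectin methylesterase (cassava4.1_023656m, at least 323-fold lower). A fold is given as a lower bound where all 3 arrays of the dimmer group were not well above background: the brighter group's mean is set against the dimmer group's mean of the higher of each array's lowest well-measured signal and the probe's own. Where 1 or 2 of its arrays were well above background, the difference is printed as measured and marked dim.

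Members of the starch list included starch branching enzyme 2.2 (cassava4.1_001701m, 3.33 ± 0.25), which makes the branch points of amylopectin, phosphoglucomutase (cassava4.1_003452m, 3.01 ± 0.24) and alpha-glucan phosphorylase 2 (cassava4.1_001626m, 2.89 ± 0.20). Of enzymes that make sucrose, sucrose phosphate synthase 1F rose by 1.97 ± 0.16 (cassava4.1_000732m) and another sucrose phosphate synthase (cassava4.1_000839m, at least 10.8-fold lower) fell, as did beta-fructofuranosidase 5 (cassava4.1_004482m, -3.72 ± 0.43), which cleaves it. Among defence genes a thaumatin-like protein (cassava4.1_012897m, at least 44.6-fold lower) fell to background, while a chitinase (cassava4.1_023221m, 2.87 ± 0.25) rose.

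Of the 27 gibberellin genes, 4 rose, 11 fell and 12 did not pass (4 and 11 over the list alone, adjusted p = 0.189), with gibberellin 2-oxidase 8 (cassava4.1_018713m, at least 71.4-fold lower) and gibberellin 2-oxidase 6 (cassava4.1_021666m, at least 16.5-fold lower), which inactivate the hormone, among the falls. Of the 165 auxin genes, 48 rose, 41 fell and 76 did not pass (48 and 42 over the list alone, adjusted p = 0.673), with median -0.06, mean 0.10 and an upward test. The auxin-inducible repressor IAA14 rose by 4.68 ± 0.30 (cassava4.1_014928m) and auxin response factor 10 by 4.80 ± 0.39 (cassava4.1_004707m, dim), whereas an auxin efflux carrier (cassava4.1_008813m, -4.49 ± 0.29) fell. Of the 27 brassinosteroid genes, 7 rose, 7 fell and 13 did not pass (7 and 7 over the list alone, adjusted p = 0.673), with a BRI1-like receptor (cassava4.1_000618m, -3.73 ± 0.26, dim) and BRI1 kinase inhibitor 1 (cassava4.1_012164m, 3.70 ± 0.37). For cytokinin, 5 rose, 10 fell and 19 did not pass (5 and 10 over the list alone, adjusted p = 0.935). For jasmonate, 20 rose, 9 fell and 29 did not pass (20 and 9 over the list alone, adjusted p = 0.384). For abscisic acid, 9 rose, 14 fell and 17 did not pass (10 and 15 over the list alone, adjusted p = 0.673). For ethylene, 15 rose, 10 fell and 17 did not pass (17 and 10 over the list alone, adjusted p = 0.384); this list also holds methylenetetrahydrofolate reductases, which belong to folate metabolism, beside the ethylene-forming enzyme (cassava4.1_012282m, -4.20 ± 0.33).

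Among the lists of structure and growth, of the 45 lignin genes, 8 rose, 23 fell and 14 did not pass (9 and 23 over the list alone, adjusted p = 0.189), with 4-coumarate:CoA ligase 1 (cassava4.1_027178m, at least 22.6-fold lower), an enzyme of lignin precursors. Of the 27 xylem genes, 8 rose, 4 fell and 15 did not pass (8 and 4 over the list alone, adjusted p = 0.466), with the vessel regulator VND1 (cassava4.1_031776m, -3.43 ± 0.31) and fasciclin-like arabinogalactan protein 6 (cassava4.1_017586m, 3.88 ± 0.50). For wall loosening, 15 rose, 26 fell and 29 did not pass (15 and 26 over the list alone, adjusted p = 0.384). For cell division, 17 rose, 22 fell and 49 did not pass (15 and 21 over the list alone, adjusted p = 0.673). For KNOX, BELL and MADS genes, 15 rose, 17 fell and 20 did not pass (15 and 17 over the list alone, adjusted p = 0.939). The D-type cyclin D3;3 rose by 2.12 ± 0.32 (cassava4.1_010382m) and a KNOTTED-like gene, of a family that keeps cells undifferentiated, by 2.19 ± 0.21 (cassava4.1_010084m), and the root MADS gene AGAMOUS-like 12 (cassava4.1_016582m, at least 17.4-fold lower) fell. For starch breakdown, 13 rose, 4 fell and 11 did not pass (13 and 4 over the list alone, adjusted p = 0.384). For sucrose, 11 rose, 14 fell and 22 did not pass (11 and 14 over the list alone, adjusted p = 0.935), with median 0.18, mean -0.19 and an upward test. The sucrose list also holds phosphofructokinases of glycolysis. For storage root proteins, 2 rose, 4 fell and 4 did not pass (3 and 4 over the list alone, adjusted p = 0.384). For latex, 1 rose, 3 fell and 2 did not pass (1 and 3 over the list alone, adjusted p = 0.466).

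For photosynthesis, 38 rose, 12 fell and 58 did not pass (37 and 11 over the list alone, adjusted p = 0.189). For phloem, 6 rose, 9 fell and 10 did not pass (6 and 9 over the list alone, adjusted p = 0.557), with the sieve-tube lectin PP2-A10 (cassava4.1_017499m, -7.45 ± 0.55, dim) lower. The phloem list also holds protein phosphatases of a like name. For heat shock, 37 rose, 63 fell and 81 did not pass (37 and 63 over the list alone, adjusted p = 0.326). For ribosomal proteins, 78 rose, 72 fell and 212 did not pass (76 and 68 over the list alone, adjusted p = 0.935), with median -0.08, mean 0.01 and an upward test. The list of suberin and periderm matched 1 gene, glycerol-3-phosphate acyltransferase 5 (cassava4.1_032628m, -1.38 ± 0.61, dim), which did not pass, and the list of cyanogenic glucosides matched 0 annotated genes.

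The test was limma on all 42 arrays, with Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold needed to pass, and camera for lists. No slide held both groups, and with slide as a fixed block 4671 probes passed, with the starch list at adjusted p = 2.35e-10 and the defence list at 0.000442.

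At week 12 the same comparison asks whether the pattern of week 8 goes on. Of starch synthesis, 30 of 42 genes rose, 3 fell and 9 did not pass (30 and 3 over the list alone, median 1.02, adjusted p = 0.00174, adjusted p = 0.718 with an estimated correlation), with starch branching enzyme 2.2 (cassava4.1_004431m, 2.82 ± 0.29) and phosphoglucomutase (cassava4.1_003452m, 2.33 ± 0.24). Of photosynthesis, 61 of 108 genes rose, 5 fell and 42 did not pass (61 and 5 over the list alone, median 0.94, adjusted p = 0.00174, adjusted p = 0.981 with an estimated correlation), with ribulose-bisphosphate carboxylase (cassava4.1_023305m, 3.03 ± 0.23) and photosystem II protein C (cassava4.1_022561m, 2.44 ± 0.21). Brassinosteroid-6-oxidase 1 and an auxin-inducible repressor were among the largest rises. A gibberellin 2-oxidase, a laccase and a patatin-like protein were far lower.

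Here 9478 probes were higher and 6847 lower (7039 and 4660 genes), around a median of all probes of 0.18, and list tests are relative to the other genes. Scaled on the 7 spike-in controls instead, with a median of -0.67, 19.6% of 19734 probes were higher, against 58.1%. The largest rises included a dynein light chain (cassava4.1_017203m, at least 68.7-fold higher), brassinosteroid-6-oxidase 1 (cassava4.1_008216m, 7.79 ± 0.53, dim) and IAA29 (cassava4.1_015494m, 7.48 ± 0.64). The largest falls included flowering promoting factor 1 (cassava4.1_027588m, at least 474-fold lower), the invertase or pectin methylesterase inhibitor (cassava4.1_023656m, at least 535-fold lower), osmotin 34 (cassava4.1_014739m, -9.66 ± 0.45) and patatin-like protein 4 (EST_GH618883, at least 193-fold lower). Gibberellin 2-oxidase 8 (cassava4.1_018713m, at least 104-fold lower), a GH3 auxin-conjugating enzyme (cassava4.1_003838m, at least 177-fold lower), cytosolic invertase 2 (cassava4.1_004783m, -2.36 ± 0.20) and laccase 5 (cassava4.1_012403m, -6.71 ± 0.59), which couples lignin monomers, fell. Cyclin D3;3 rose by 3.49 ± 0.32 and a KNOTTED-like gene by 2.55 ± 0.21. The suberin enzyme glycerol-3-phosphate acyltransferase 5 fell (-6.37 ± 0.61, dim). Each group lay on a slide of its own, so slide and tissue cannot be told apart here.

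**Figure D2:**
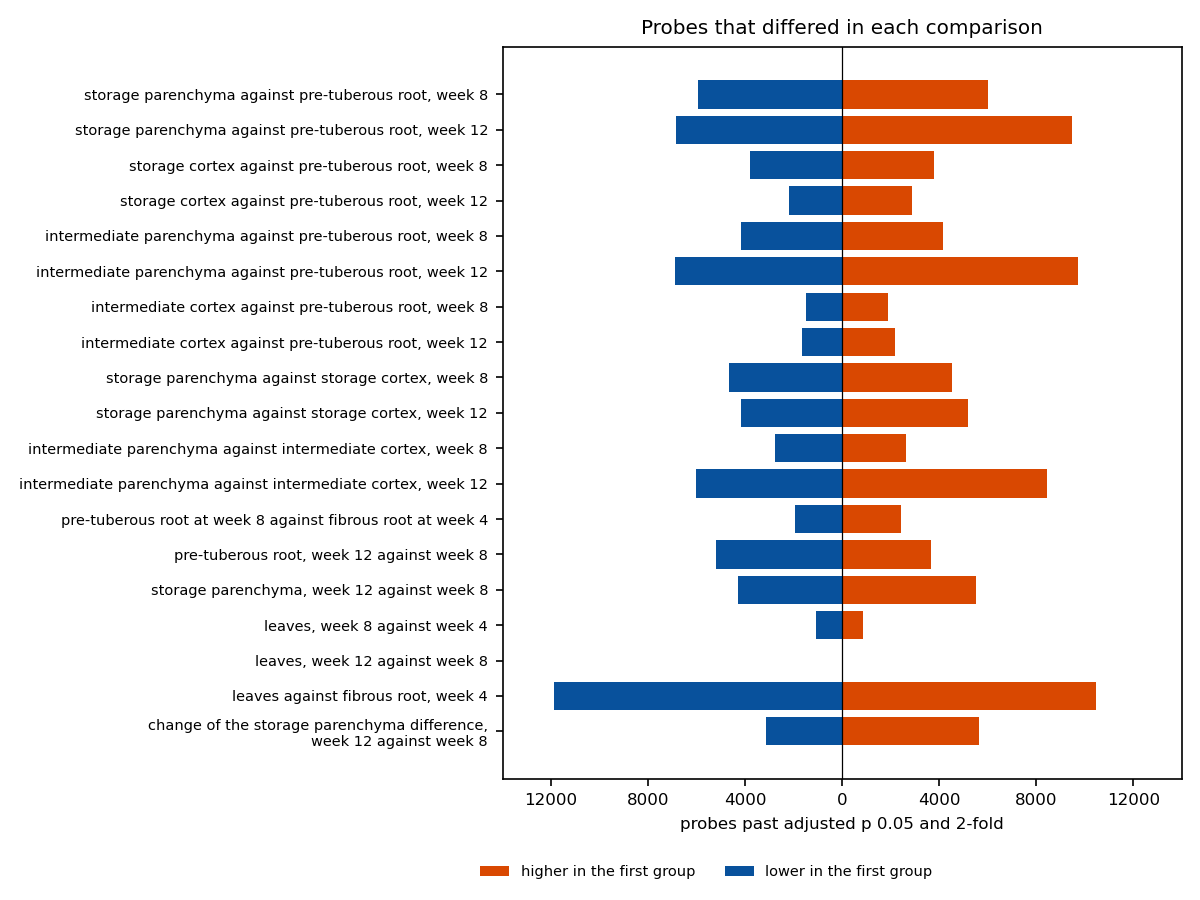
Probes past both thresholds (adjusted p under 0.05, at least 2-fold) in each of the 19 comparisons (vertical), higher in the first-named group to the right and lower to the left (horizontal, number of probes). Leaves against fibrous root had the most, 22330, and leaves of week 12 against week 8 the fewest, 45. On spike-in scaling the split turns for several comparisons.

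The difference between both weeks' changes was tested as an interaction. The program of the storage tissue was largely shared: across probes, which are not independent replicates, the log2 differences of weeks 8 and 12 correlated at Pearson's r = 0.725. Of the 7999 probes past both thresholds at both weeks, 4157 were higher at both and 3507 lower at both, where independent lists would give 1372 and 979. Another 335 went opposite ways (2346 by independence), 236 of them lower at week 8 and higher at week 12.

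The change itself differed for 8770 probes, 5617 towards higher and 3153 towards lower at week 12, around a median of 0.16 (19721 with dim probes included, 10448 of them dim, and 5564 at an adjusted p under 0.01). Of the 8770, 4927 were well above background on all 12 arrays. On spike-in scaling, with a median of -0.78, 7.8% of 12383 probes went higher, against 64%, and 46.4% with quantile normalization and 76.8% with normexp. Of starch synthesis, 3 of 42 genes rose, 12 fell and 27 did not pass (3 and 13 over the list alone, median -0.28, adjusted p = 0.00309, adjusted p = 0.672 with an estimated correlation), and with normexp its median was 0.00. No other list fixed beforehand passed. The change of starch branching enzyme 2.2 (cassava4.1_001701m, -1.10 ± 0.35), alpha-glucan phosphorylase 2 (cassava4.1_001626m, -1.18 ± 0.28) and cyclin D3;3 (cassava4.1_010382m, 1.37 ± 0.45) is given as the later difference minus the earlier one. The 12 arrays lay on slides of which none held both tissues of a week, and with slide as a random block 8359 probes passed.

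Storage parenchyma was set against storage cortex to ask how the inner and outer tissues of a thickened root differ. At week 8, of starch synthesis, 21 of 42 genes rose, 2 fell and 19 did not pass (25 and 2 over the list alone, median 0.64, adjusted p = 0.000172, adjusted p = 0.361 with an estimated correlation), with ADP-glucose pyrophosphorylase (cassava4.1_006048m, 2.57 ± 0.35), which commits glucose to starch, and glucose-6-phosphate translocator 2 (cassava4.1_009081m, 3.62 ± 0.50, dim), which brings sugar into plastids. Of cell division, 6 of 88 genes rose, 39 fell and 43 did not pass (6 and 40 over the list alone, median -0.49, adjusted p = 0.000479, adjusted p = 0.361 with an estimated correlation), with cyclin D3;1 (cassava4.1_009900m, -2.52 ± 0.37) and cyclin D3;2 (cassava4.1_010147m, -2.04 ± 0.30). The transcript of brassinosteroid-6-oxidase 1 was higher in parenchyma.

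At week 8, 4527 probes were higher and 4667 lower in parenchyma. Scaled on spike-ins, with a median of 0.51, 75.9% of 12015 probes were higher, and with normexp 39%, against 49.2%. The largest rises included an aspartyl protease (cassava4.1_009485m, 7.24 ± 0.74, dim), an HXXXD-type acyltransferase (cassava4.1_007546m, at least 47.6-fold higher) and a SAUR-like auxin-responsive protein (cassava4.1_033618m, at least 18.8-fold higher), and the largest falls a polyketide cyclase (cassava4.1_029339m, -9.26 ± 0.74, dim), MLP-like protein 28 (cassava4.1_025463m, -9.09 ± 0.69, dim) and early nodulin-like protein 9 (cassava4.1_016274m, at least 94-fold lower). Of gibberellin, 4 of 27 genes rose, 13 fell and 10 did not pass (4 and 14 over the list alone, median -0.99, adjusted p = 0.0438, adjusted p = 0.524 with an estimated correlation), with ent-kaurenoic acid hydroxylase 2 (cassava4.1_006198m, at least 5.33-fold lower), an enzyme of gibberellin synthesis, and gibberellin 2-oxidase 8 (cassava4.1_018713m, at least 6.36-fold lower). Of xylem and secondary wall, 16 of 27 genes rose, 5 fell and 6 did not pass (16 and 5 over the list alone, median 0.98, adjusted p = 0.0468, adjusted p = 0.656 with an estimated correlation), with xylem cysteine peptidase 2 (cassava4.1_010750m, 5.23 ± 0.74), which clears dying vessel cells.

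Of storage root proteins, 0 of 10 genes rose, 5 fell and 5 did not pass (0 and 5 over the list alone, median -0.56, adjusted p = 0.0438, adjusted p = 0.361 with an estimated correlation), with patatin-like protein 6 (cassava4.1_006837m, -2.04 ± 0.18). Of wounding and defence, 12 of 69 genes rose, 28 fell and 29 did not pass (14 and 28 over the list alone, median -0.21, adjusted p = 0.00928, adjusted p = 0.361 with an estimated correlation), with a basic chitinase (cassava4.1_011797m, -7.80 ± 0.56, dim). Of ribosomal proteins, 133 of 362 genes rose, 9 fell and 220 did not pass (133 and 9 over the list alone, median 0.36, adjusted p = 3.19e-05, adjusted p = 0.718 with an estimated correlation), with ribosomal protein S3 (cassava4.1_012999m, 1.43 ± 0.16). Brassinosteroid-6-oxidase 1 rose by 3.17 ± 0.53. On spike-in scaling the median of the wounding and defence list turned to 0.24. With slide as a fixed block 8003 probes passed, and the gibberellin (adjusted p = 0.0533), xylem (0.227), storage root protein (0.0762), wounding (0.0533) and ribosomal (0.0533) lists did not, at medians of -1.55, 0.57, -0.70, -0.22 and 0.17. Normexp ended the gibberellin (adjusted p = 0.13, median -0.29) and storage root protein (0.144, median -0.48) calls, all probes of the list ended the latter (0.154, median 0.23), and the xylem call ended with quantile normalization (0.0618, median 0.97) and spike-in scaling (0.0597, median 1.42). The replicate numbers paired these samples.

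At week 12 the same tissues were compared. A pair of homeobox genes were among the largest rises in parenchyma, and a gibberellin 2-oxidase and a D-type cyclin were again lower there than in cortex. The starch synthesis list did not pass.

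Here 5179 probes were higher and 4195 lower, around a median of 0.12. On spike-in scaling, with a median of -0.65, 9.2% of 14043 probes were higher, against 55.2%. The largest rises included a KNOX homeobox gene (cassava4.1_021832m, at least 31.9-fold higher), homeobox protein 52 (cassava4.1_030094m, 5.36 ± 0.69, dim) and a dehydrin (cassava4.1_018057m, at least 40.6-fold higher), and the largest falls flowering promoting factor 1 (cassava4.1_027588m, at least 66.5-fold lower), an EF-hand protein (cassava4.1_018450m, at least 77-fold lower) and a thioredoxin (cassava4.1_021286m, at least 38.4-fold lower). Of starch synthesis, 17 of 42 genes rose, 1 fell and 24 did not pass (17 and 1 over the list alone, median 0.49, adjusted p = 0.0792), with phosphoglucomutase (cassava4.1_003452m, 1.18 ± 0.24), and 0 of the 22 lists passed by camera. Cyclin D3;1 (cassava4.1_009900m, -3.81 ± 0.37), gibberellin 2-oxidase 8 (cassava4.1_018713m, at least 26.6-fold lower), cinnamyl alcohol dehydrogenase 6 (cassava4.1_010332m, -5.86 ± 0.70) and VND1 (cassava4.1_031776m, -2.71 ± 0.31) fell, and ribulose-bisphosphate carboxylase rose by 2.48 ± 0.23. Both weeks shared 4185 probes, 1986 higher and 1845 lower at both (565 and 472 by independence), with r = 0.523 across probes. All 6 arrays lay on slide 4. A fit on it, with intermediate parenchyma, gave 9042 probes. Without cortex replicate 1, which lay apart, 6887 passed.

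Storage cortex was set against pre-tuberous root to ask what the outer tissue gains. At week 8, of starch synthesis, 26 of 42 genes rose, 1 fell and 15 did not pass (26 and 1 over the list alone, median 0.71, adjusted p = 7.74e-07, adjusted p = 0.214 with an estimated correlation), with a glucose-6-phosphate translocator (cassava4.1_024254m, 2.40 ± 0.28). At week 12, of starch synthesis, 15 of 42 genes rose, 1 fell and 26 did not pass (17 and 2 over the list alone, median 0.42, adjusted p = 0.000423, adjusted p = 0.975 with an estimated correlation), with ADP-glucose pyrophosphorylase (cassava4.1_006048m, 2.20 ± 0.35) and starch branching enzyme 2.2 (cassava4.1_004431m, 2.22 ± 0.29).

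At week 8, 3767 probes were higher and 3809 lower. With spike-in scaling and a median of -0.42, 22.4% of 8702 probes were higher, against 49.7%. A NAC transcription factor (cassava4.1_027454m, at least 29.1-fold higher) was among the largest rises, and a pectin lyase-like protein (cassava4.1_027248m, at least 555-fold lower), an aspartyl protease (cassava4.1_009485m, -9.23 ± 0.74, dim) and expansin-like A2 (cassava4.1_030380m, -8.85 ± 0.68, dim) among the largest falls. Of jasmonate, 20 of 58 genes rose, 6 fell and 32 did not pass (21 and 7 over the list alone, median 0.53, adjusted p = 0.0104, adjusted p = 0.895 with an estimated correlation), with a lipoxygenase (cassava4.1_001616m, 2.53 ± 0.36). Of cell division, 30 of 88 genes rose, 5 fell and 53 did not pass (31 and 5 over the list alone, median 0.42, adjusted p = 0.00175, adjusted p = 0.63 with an estimated correlation), with phragmoplast orienting kinesin 1 (cassava4.1_031605m, at least 3.01-fold higher), which places the new cell wall, and cyclin A2;3 (cassava4.1_030070m, at least 2.04-fold higher). Of lignin, 5 of 45 genes rose, 21 fell and 19 did not pass (6 and 23 over the list alone, median -0.91, adjusted p = 0.00194, adjusted p = 0.63 with an estimated correlation), with cinnamate-4-hydroxylase (cassava4.1_005452m, -4.00 ± 0.49). Of ribosomal proteins, 19 of 362 genes rose, 152 fell and 191 did not pass (20 and 166 over the list alone, median -0.42, adjusted p = 1.61e-06, adjusted p = 0.895 with an estimated correlation), with ribosomal protein L15 (cassava4.1_013486m, -1.07 ± 0.17). No slide held both groups, and with slide as a fixed block 827 probes passed and the cell division list did not (adjusted p = 0.0869, median 0.31).

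At week 12, 2889 probes were higher and 2181 lower, and 46.5% of 2334 higher with normexp, against 57%. The largest rises included cytochrome P450 79B2 (cassava4.1_005059m, 6.46 ± 1.01), an HXXXD-type acyltransferase (cassava4.1_007546m, 5.10 ± 0.53, dim) and lipoxygenase 2 (cassava4.1_001332m, 4.95 ± 0.62), of jasmonate synthesis. The largest falls included Kunitz trypsin inhibitor 1 (cassava4.1_022744m, -4.62 ± 0.86), a cupin (cassava4.1_034372m, at least 13.3-fold lower) and MLP-like protein 43 (cassava4.1_018249m, -4.19 ± 0.74, dim). Of photosynthesis, 30 of 108 genes rose, 2 fell and 76 did not pass (32 and 2 over the list alone, median 0.51, adjusted p = 6.34e-05, adjusted p = 0.975 with an estimated correlation). Of lignin, 5 of 45 genes rose, 17 fell and 23 did not pass (5 and 19 over the list alone, median -0.17, adjusted p = 0.027, adjusted p = 0.975 with an estimated correlation), with 4-coumarate:CoA ligase 5 (cassava4.1_032782m, -2.97 ± 0.56). The numbers paired these samples, and slide and tissue cannot be told apart. The count ranged with the samples: 6830 without cortex replicate 1, 2937 without cortex replicate 3 and 3315 without pre-tuberous replicate 1. Both weeks shared 2089 probes, 992 higher at both and 778 lower at both (262 and 200 by independence), with r = 0.326 across probes.

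Intermediate parenchyma was set against pre-tuberous root to ask how much of the change precedes full thickening. At week 8, of starch synthesis, 24 of 42 genes rose, 3 fell and 15 did not pass (25 and 3 over the list alone, median 0.67, adjusted p = 1.42e-05, adjusted p = 0.404 with an estimated correlation), with phosphoglucomutase (cassava4.1_003452m, 1.85 ± 0.24). At week 12, of starch synthesis, 28 of 42 genes rose, 3 fell and 11 did not pass (29 and 3 over the list alone, median 1.01, adjusted p = 0.00168, adjusted p = 0.738 with an estimated correlation), with starch branching enzyme 2.2 (cassava4.1_004431m, 3.08 ± 0.29).

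At week 8, 4170 probes were higher and 4160 lower, with the CENTRORADIALIS homologue (cassava4.1_017618m, at least 63.4-fold higher), of a family that delays flowering, and myb40 (cassava4.1_031140m, at least 18.1-fold higher) among the largest rises and beta glucosidase 17 (cassava4.1_005099m, -6.34 ± 0.57, dim) and a thioredoxin (cassava4.1_033785m, -5.92 ± 0.91, dim) among the falls. Of photosynthesis, 48 of 108 genes rose, 8 fell and 52 did not pass (51 and 10 over the list alone, median 0.60, adjusted p = 0.000873, adjusted p = 0.811 with an estimated correlation), with the oxygen-evolving complex protein 1 (cassava4.1_011470m, at least 7.83-fold higher). Brassinosteroid-6-oxidase 1 (cassava4.1_008216m, at least 40-fold higher) and IAA9 (cassava4.1_010103m, 1.84 ± 0.20) rose and gibberellin 2-oxidase 8 (cassava4.1_018713m, -4.47 ± 0.56) fell. The numbers paired these samples. No slide held both groups, and with slide as a fixed block 1515 probes passed, with both lists still called (adjusted p = 4.26e-05 and 0.000382).

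At week 12, 9709 probes were higher and 6906 lower, around a median of 0.17. On spike-in scaling, with a median of -0.69, 21.3% of 20328 probes were higher, against 58.4%. The dynein light chain (cassava4.1_017203m, at least 81-fold higher) and IAA29 (cassava4.1_015494m, 7.80 ± 0.64) were again among the largest rises, and flowering promoting factor 1 (cassava4.1_027588m, at least 488-fold lower) and the invertase or pectin methylesterase inhibitor (cassava4.1_023656m, at least 551-fold lower) among the falls. Of photosynthesis, 61 of 108 genes rose, 5 fell and 42 did not pass (61 and 5 over the list alone, median 0.87, adjusted p = 0.00168, adjusted p = 0.964 with an estimated correlation), with photosystem II protein C (cassava4.1_022561m, 3.26 ± 0.21). The parenchyma lay on slides 4 and 5 and the thin root on slide 3, and with slide as a random block 16564 probes passed.

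Intermediate cortex was likewise set against pre-tuberous root. At week 8, of starch synthesis, 15 of 42 genes rose, 0 fell and 27 did not pass (19 and 2 over the list alone, median 0.42, adjusted p = 7.22e-05, adjusted p = 0.585 with an estimated correlation), with ADP-glucose pyrophosphorylase (cassava4.1_006048m, 1.51 ± 0.35). At week 12, of starch synthesis, 13 of 42 genes rose, 2 fell and 27 did not pass (14 and 2 over the list alone, median 0.32, adjusted p = 0.00137, adjusted p = 0.756 with an estimated correlation), with ADP-glucose pyrophosphorylase (cassava4.1_006360m, 3.01 ± 0.38).

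At week 8, 1903 probes were higher and 1499 lower. Scaled on spike-ins, with a median of -0.36, 26.5% of 2515 probes were higher, against 55.9%. A leucine-rich receptor kinase (cassava4.1_000643m, at least 8.92-fold higher) and a cupin (cassava4.1_034372m, 4.72 ± 0.96, dim) were among the largest rises, and the pectin lyase-like protein (cassava4.1_027248m, -10.12 ± 0.64, dim) and beta glucosidase 29 (cassava4.1_028771m, -7.89 ± 0.59) among the largest falls. Of cell division, 16 of 88 genes rose, 5 fell and 67 did not pass (22 and 8 over the list alone, median 0.33, adjusted p = 0.0106, adjusted p = 0.915 with an estimated correlation), with phragmoplast orienting kinesin 1 (cassava4.1_031605m, at least 2.37-fold higher). Of photosynthesis, 19 of 108 genes rose, 4 fell and 85 did not pass (23 and 4 over the list alone, median 0.23, adjusted p = 0.0106, adjusted p = 0.915 with an estimated correlation), and on spike-in scaling its median turned to -0.04. Xylem cysteine peptidase 2 (cassava4.1_010750m, -4.92 ± 0.74) and the vessel regulator VND7 (cassava4.1_027686m, -3.15 ± 0.51) fell. The numbers paired these samples. With slide as a fixed block 2104 probes passed, on slide 1 alone 2095, and without cortex replicate 3 2116.

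At week 12, 2151 probes were higher and 1669 lower, with a peroxidase (cassava4.1_011738m, 5.91 ± 0.71, dim) and gibberellin 2-oxidase 8 (cassava4.1_011624m, 5.60 ± 0.95, dim) among the largest rises and the pectin lyase-like protein (cassava4.1_027248m, at least 479-fold lower) and osmotin 34 (cassava4.1_030758m, -9.91 ± 0.74, dim) among the falls. Of lignin, 0 of 45 genes rose, 7 fell and 38 did not pass (1 and 10 over the list alone, median -0.14, adjusted p = 0.0227, adjusted p = 0.756 with an estimated correlation), with cinnamate-4-hydroxylase (cassava4.1_005452m, -4.77 ± 0.49). Of photosynthesis, 19 of 108 genes rose, 2 fell and 87 did not pass (21 and 2 over the list alone, median 0.43, adjusted p = 0.00147, adjusted p = 0.756 with an estimated correlation). Of ribosomal proteins, 40 of 362 genes rose, 6 fell and 316 did not pass (34 and 4 over the list alone, median 0.21, adjusted p = 0.00137, adjusted p = 0.99 with an estimated correlation), with ribosomal protein L6 (cassava4.1_015589m, 1.47 ± 0.32). Lipoxygenase 2 (cassava4.1_001332m, 5.26 ± 0.62) and cyclin D3;1 (cassava4.1_009900m, 2.03 ± 0.37) rose. With slide as a fixed block 3846 probes passed, on slide 3 alone 2628, and without pre-tuberous replicate 1 2291.

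Intermediate parenchyma was set against intermediate cortex to ask when the tissues part. At week 8, of xylem and secondary wall, 15 of 27 genes rose, 0 fell and 12 did not pass (15 and 0 over the list alone, median 0.99, adjusted p = 0.000854, adjusted p = 0.556 with an estimated correlation), with xylem cysteine peptidase 2 (cassava4.1_010750m, 5.49 ± 0.74). Of cell division, 2 of 88 genes rose, 24 fell and 62 did not pass (2 and 24 over the list alone, median -0.35, adjusted p = 0.00118, adjusted p = 0.585 with an estimated correlation), with cyclin D3;1 (cassava4.1_009900m, -2.62 ± 0.37) and the cell-cycle kinase CDKB1;1 (cassava4.1_012120m, -1.59 ± 0.28). At week 12, 0 of the 22 lists passed by camera, and a KNOX gene and an auxin response factor were higher in parenchyma and a D-type cyclin and a gibberellin 2-oxidase higher in cortex.

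At week 8, 2625 probes were higher and 2779 lower. On spike-in scaling 62.6% of 4675 were higher, against 48.6%. The pectin lyase-like protein (cassava4.1_027248m, 9.40 ± 0.64, dim) and the SAUR-like protein (cassava4.1_033618m, at least 53.1-fold higher) were among the largest rises, and a cupin (cassava4.1_034372m, -5.97 ± 0.96) and a laccase (cassava4.1_028126m, at least 18.6-fold lower) among the largest falls. Of storage root proteins, 0 of 10 genes rose, 5 fell and 5 did not pass (1 and 6 over the list alone, median -0.80, adjusted p = 0.0475, adjusted p = 0.325 with an estimated correlation), and over all probes of the list it did not pass (adjusted p = 0.172, median -0.43). The numbers paired these samples. Parenchyma lay on slide 2 with 1 cortex array, and with slide as a fixed block 2825 probes passed, with the xylem, cell division and storage root protein lists still called (adjusted p = 0.00727, 1.72e-05 and 0.0441).

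At week 12, 8430 probes were higher and 6016 lower, around a median of 0.15. On spike-in scaling, with a median of -0.72, 17.4% of 19159 were higher, against 58.4%. The dynein light chain (cassava4.1_017203m, at least 83.2-fold higher) and a tyrosine transaminase (cassava4.1_016409m, at least 50.1-fold higher) were among the largest rises, and flowering promoting factor 1 (cassava4.1_027588m, at least 95.4-fold lower) and a thioredoxin (cassava4.1_033785m, at least 93.2-fold lower) among the largest falls. Auxin response factor 10 (cassava4.1_004707m, 4.96 ± 0.39), the KNOX gene KNAT6 (cassava4.1_022137m, at least 9.05-fold higher), xylem cysteine peptidase 2 (cassava4.1_010750m, 5.69 ± 0.74) and phosphoglucomutase (cassava4.1_003452m, 2.49 ± 0.24) rose, and cyclin D3;1 (cassava4.1_009900m, -4.47 ± 0.37) and gibberellin 2-oxidase 8 (cassava4.1_018713m, at least 37.1-fold lower) fell. The glycerol-3-phosphate acyltransferase 5 gene of suberin fell (-5.05 ± 0.61, dim). Both weeks shared 3952 probes, 2031 higher at both and 1790 lower at both (533 and 403 by independence), with r = 0.642 across probes. No slide held both tissues, and with slide as a random block 14386 probes passed.

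**Figure D3:**
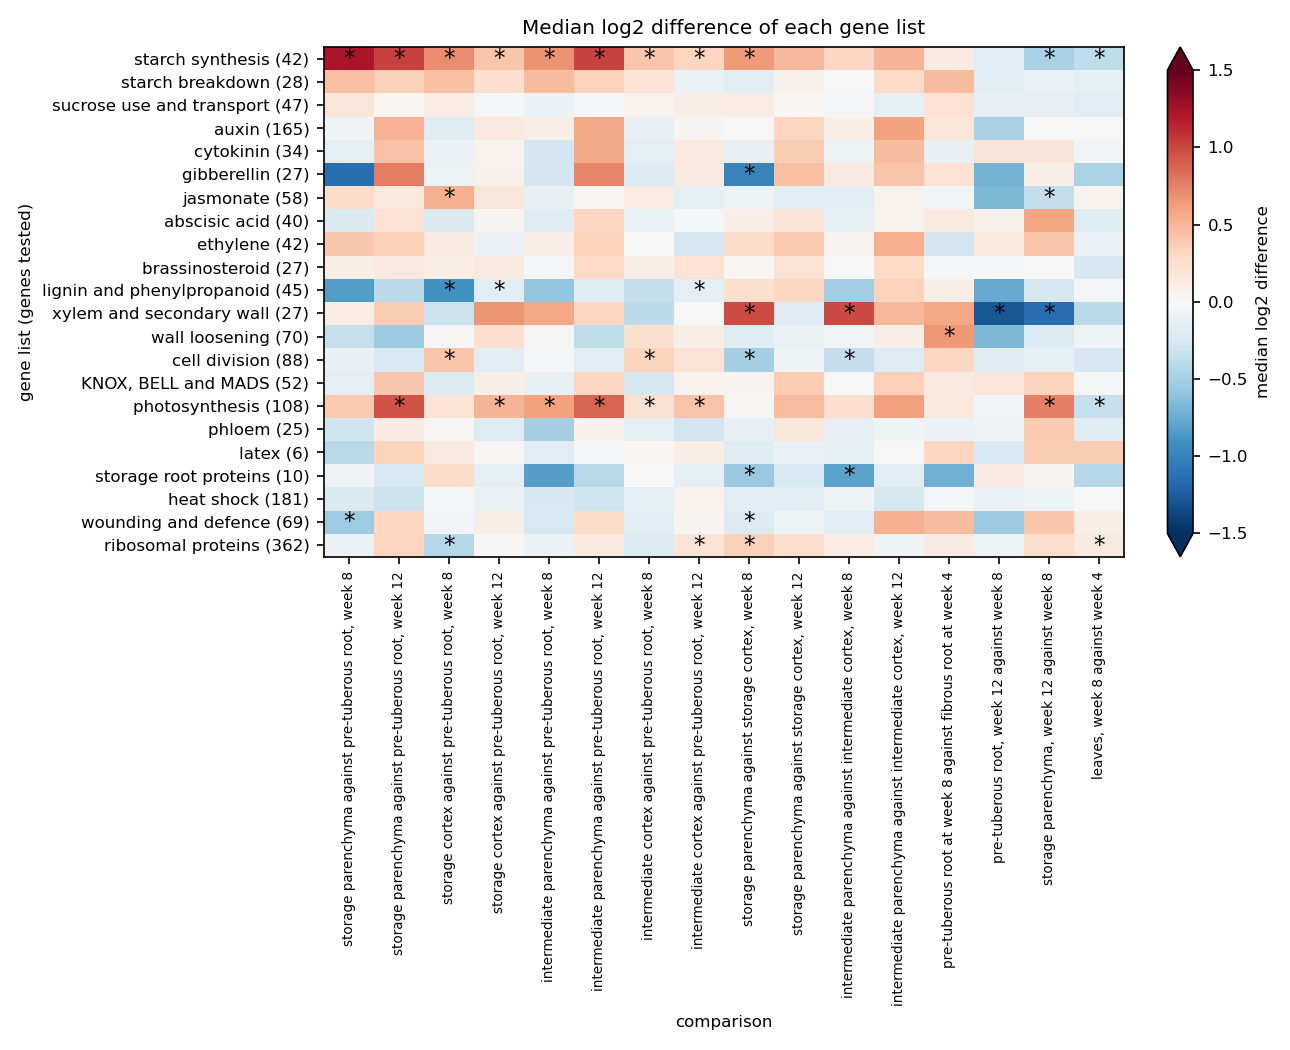
Median log2 difference (colour, held within ±1.5) of the 22 lists fixed beforehand (vertical) in 16 comparisons (horizontal, the last of leaves). An asterisk marks an adjusted p under 0.05 by camera with a preset correlation. Starch synthesis was highest for storage parenchyma of week 8, at 1.22. With an estimated correlation only that call here passed. Counting added lists, spike-in scaling turned the sign of 3 medians for storage parenchyma against pre-tuberous root at week 8 and of 20 at week 12.

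Thin roots were compared over time to ask what changes before and beside thickening. From fibrous root at week 4 to pre-tuberous root at week 8, of wall loosening, 16 of 70 genes rose, 2 fell and 52 did not pass (19 and 2 over the list alone, median 0.65, adjusted p = 0.0169, adjusted p = 0.734 with an estimated correlation), with expansin A5 (cassava4.1_014803m, 3.92 ± 0.50) and expansin A15 (cassava4.1_014489m, 2.91 ± 0.48). From week 8 to week 12, of xylem and secondary wall, 1 of 27 genes rose, 15 fell and 11 did not pass (1 and 15 over the list alone, median -1.28, adjusted p = 0.00722, adjusted p = 0.907 with an estimated correlation), with xylem cysteine peptidase 2 (cassava4.1_010750m, -4.51 ± 0.74) and fasciclin-like arabinogalactan protein 11 (cassava4.1_015233m, -3.92 ± 0.69, dim).

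Pre-tuberous root of week 8 had 2424 probes higher and 1940 lower than fibrous root. With spike-in scaling and a median of -0.33, 22.2% of 4133 were higher, against 55.5%. A peroxidase (cassava4.1_024068m, 5.63 ± 0.62, dim) and pyruvate decarboxylase 2 (cassava4.1_003934m, 5.11 ± 0.56), of fermentation, were among the largest rises, and senescence-associated gene 12 (cassava4.1_032151m, -9.36 ± 0.73, dim) and chitinase A (cassava4.1_023457m, -9.05 ± 0.89, dim) among the largest falls. Both groups lay on slide 1. A fit on that slide, which also took in its intermediate cortex arrays of week 8, gave 4419 probes.

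Pre-tuberous root of week 12 had 3653 probes higher and 5197 lower than at week 8, and 57.3% of 7672 higher on spike-in scaling, against 41.3%. An ABC transporter (cassava4.1_002248m, 7.74 ± 0.72, dim) was among the largest rises, and caffeoyl-CoA 3-O-methyltransferase (cassava4.1_026116m, at least 19-fold lower), of lignin synthesis, and a wound-responsive protein (cassava4.1_020294m, -5.73 ± 0.98) among the largest falls. The suberin enzyme glycerol-3-phosphate acyltransferase 5 rose by 5.96 ± 0.61. No slide held both groups, and with slide as a fixed block 2576 probes passed, with the xylem list at adjusted p = 0.000291.

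Storage parenchyma was compared between weeks to ask what changes as the organ ages. Of starch synthesis, 4 of 42 genes rose, 18 fell and 20 did not pass (4 and 20 over the list alone, median -0.49, adjusted p = 0.000125, adjusted p = 0.287 with an estimated correlation), with ADP-glucose pyrophosphorylase (cassava4.1_006360m, -3.40 ± 0.38) and glucose-6-phosphate translocator 2 (cassava4.1_009081m, at least 7.27-fold lower). Of jasmonate, 7 of 58 genes rose, 25 fell and 26 did not pass (9 and 27 over the list alone, median -0.36, adjusted p = 0.000239, adjusted p = 0.51 with an estimated correlation), with allene oxide cyclase 3 (cassava4.1_026961m, at least 28.9-fold lower) and JAZ8 (cassava4.1_019045m, -4.63 ± 0.56). Of xylem and secondary wall, 0 of 27 genes rose, 15 fell and 12 did not pass (0 and 16 over the list alone, median -1.14, adjusted p = 1.24e-05, adjusted p = 0.287 with an estimated correlation), with VND7 (cassava4.1_034391m, at least 9.06-fold lower). Of photosynthesis, 54 of 108 genes rose, 3 fell and 51 did not pass (56 and 3 over the list alone, median 0.76, adjusted p = 0.000109, adjusted p = 0.51 with an estimated correlation), with a light-harvesting protein (cassava4.1_013714m, 5.01 ± 0.38), and on spike-in scaling its median was -0.01. At week 12, 5504 probes were higher and 4296 lower, around a median of 0.14, and on spike-in scaling, with a median of -0.63, 12.3% of 14142 were higher, against 56.2%. A glycosyl hydrolase (cassava4.1_009799m, 8.31 ± 0.90, dim) was among the largest rises, and a bHLH factor (cassava4.1_026244m, at least 35.1-fold lower) and ACC synthase 1 (cassava4.1_028340m, at least 27.5-fold lower), which makes the precursor of ethylene, among the largest falls. The weeks lay on different slides, and with slide as a random block 9727 probes passed.

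Leaves were compared between weeks as the tissue that supplies the sugar. At week 8 against week 4, of starch synthesis, 1 of 42 genes rose, 8 fell and 33 did not pass (1 and 9 over the list alone, median -0.39, adjusted p = 0.0029, adjusted p = 0.584 with an estimated correlation), with alpha-glucan phosphorylase 2 (cassava4.1_002082m, -1.32 ± 0.26). Of photosynthesis, 2 of 108 genes rose, 4 fell and 102 did not pass (1 and 4 over the list alone, median -0.34, adjusted p = 0.00559, adjusted p = 0.584 with an estimated correlation), with photosystem I subunit P (cassava4.1_018654m, -1.21 ± 0.21, dim). On spike-in scaling these medians turned to 0.35 and 0.39, and quantile normalization ended the photosynthesis call (adjusted p = 0.0546, median -0.14). Of ribosomal proteins, 19 of 362 genes rose, 12 fell and 331 did not pass (11 and 8 over the list alone, median 0.13, adjusted p = 0.00385, adjusted p = 0.73 with an estimated correlation). At week 8, 848 probes were higher and 1077 lower. The split moved with the scaling, from 44.1% higher to 98.3% of 7795 on spike-in controls (median 0.66), 60.1% of 682 with normexp and 54.7% with quantile normalization. Beta glucosidase 29 (cassava4.1_028771m, at least 28.6-fold higher) and a thioredoxin (cassava4.1_027873m, 5.30 ± 0.49) were among the largest rises, and the shikimate pathway enzyme dehydroquinate dehydratase (cassava4.1_004545m, at least 4.79-fold lower) among the largest falls. All 6 arrays lay on slide 5, and these alone gave 152 probes, and 1241 passed without leaf replicate 2 of week 8.

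Between weeks 8 and 12, 18 probes were higher and 27 lower, with an exonuclease (cassava4.1_025846m, 2.64 ± 0.48) among the rises and ethylene responsive element binding factor 1 (cassava4.1_022027m, -2.26 ± 0.40, dim) among the falls. Of photosynthesis, 0 of 108 genes rose, 0 fell and 108 did not pass (0 and 0 over the list alone, median 0.15, adjusted p = 0.00597, adjusted p = 0.89 with an estimated correlation), and with slide as a fixed block it did not pass (adjusted p = 0.904, median 0.04). That block left 19 probes, and 19 to 74 passed when 1 array was left out, the lowest without week 8 replicate 1 and the highest without week 8 replicate 3. Fitted on these 6 arrays alone, limma gave 0 probes, with 4156 at an unadjusted p under 0.05, and spike-in scaling gave 13 (61.5% higher) and normexp 14 (50% higher), against 40%.

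Leaves were also set against fibrous root at week 4, as a reference for a green organ. Of photosynthesis, 98 of 108 genes rose, 5 fell and 5 did not pass (99 and 5 over the list alone, median 7.12, adjusted p = 1.46e-32, adjusted p = 0.00499 with an estimated correlation), the largest shift of any list. Of starch synthesis, 28 of 42 genes rose, 8 fell and 6 did not pass (28 and 8 over the list alone, median 1.85, adjusted p = 0.000374, adjusted p = 0.281 with an estimated correlation), with starch synthase 2 (cassava4.1_002278m, 4.91 ± 0.16). Of starch breakdown, 16 of 28 genes rose, 5 fell and 7 did not pass (16 and 5 over the list alone, median 1.00, adjusted p = 0.0164, adjusted p = 0.207 with an estimated correlation), with a beta-amylase (cassava4.1_034006m, at least 307-fold higher). Of ethylene, 8 of 42 genes rose, 27 fell and 7 did not pass (8 and 27 over the list alone, median -1.34, adjusted p = 0.0229, adjusted p = 0.281 with an estimated correlation), with ethylene responsive element binding factor 1 (cassava4.1_013138m, -6.96 ± 0.28), a call that ended on spike-in scaling (adjusted p = 0.0608, median -2.30). Of ribosomal proteins, 64 of 362 genes rose, 252 fell and 46 did not pass (64 and 254 over the list alone, median -1.22, adjusted p = 0.000194, adjusted p = 0.913 with an estimated correlation). Here 10443 probes were higher and 11887 lower, around a median of -0.17, and on spike-in scaling, with a median of -1.13, 23.1% of 28400 were higher, against 46.8%. A light-harvesting protein of photosystem I (cassava4.1_014926m, 14.92 ± 0.79, dim) and photosystem II protein BY (cassava4.1_016712m, at least 7353-fold higher) were among the largest rises, and an aspartyl protease (cassava4.1_028503m, at least 5013-fold lower) and expansin-like B1 (cassava4.1_014840m, at least 4390-fold lower) among the largest falls. Slide and organ cannot be told apart in this comparison.

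**Figure D4:**
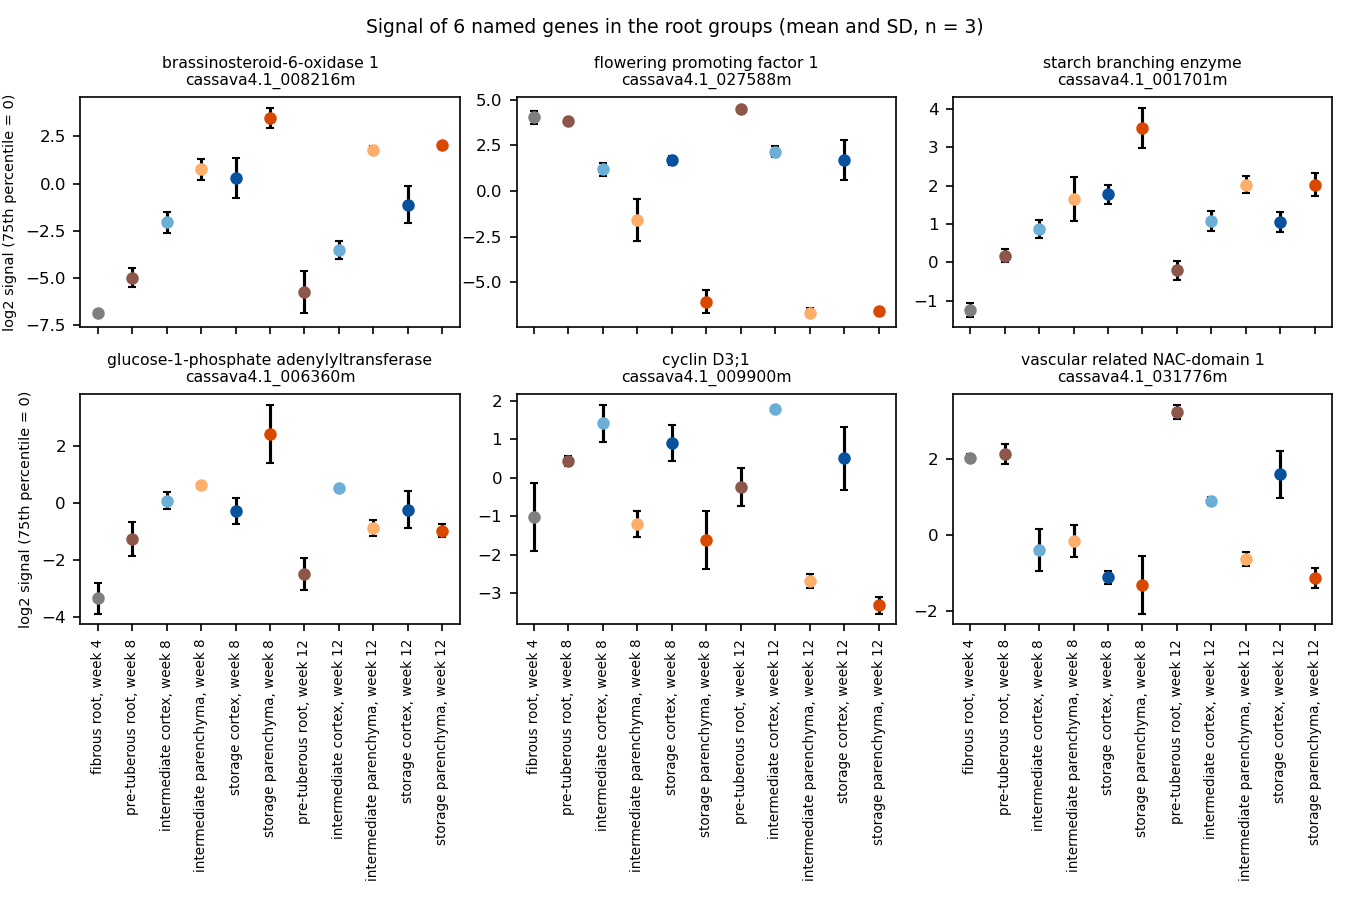
Level (vertical, log2 intensity minus the array's 75th percentile) of 6 genes in the 11 root groups (horizontal), mean and SD of n = 3 arrays. Brassinosteroid-6-oxidase 1 lies at -4.98, near background, in pre-tuberous root and 3.48 in storage parenchyma of week 8, and at -5.73 (1 of its 3 arrays well above background) and 2.06 at week 12.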

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

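The splits of the samples, the tests of the background level, the slide and mislabelling tests of the storage cortex, and the spread, exchange and scaling tests of the parenchyma were chosen only after the result was seen. A pair of results stood out because the week changed a difference between the same tissues: the contrast of storage parenchyma with pre-tuberous root changed between weeks 8 and 12 for 8770 probes, and the starch synthesis list changed with an adjusted p of 0.00309 (0.000326 to 0.672 over all alternatives, the highest with an estimated correlation).

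The first pattern is this change at 8770 probes: a difference between the scan days would move storage cortex, scanned on the same days, as much, but the change there was a median share of 0.392 of that in parenchyma (quartiles 0.106 to 0.684, with 81.7% of probes in the same direction), which argues against the scan day as the whole cause. Scaling stays open as a source of part of it, since under spike-in scaling 47% of these probes still passed in the same direction, against 99.7% with median centring, 75.5% with quantile normalization and 62.8% with normexp. A shift of the background level is argued against as the whole cause, since 56.2% of the probes were well above background on all 12 arrays, but stays open for the other 3843, as without a filter 10448 of 17567 dim probes passed, 99.4% of them higher, with a median change of 1.32 over all dim probes. Of 100 splits of the 12 arrays, 12 gave as many probes, the real one among them. The highest other, with the week 8 labels exchanged whole, gave 22468. All 12 kept the tissue difference of at least 1 week, which alone gives many probes, so this count cannot exclude chance. The 85 that kept neither week's gave at most 2. A change of the tissues with age is among the open explanations and was not tested apart from these.

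The second pattern is that storage cortex replicates 2 and 3 of week 12 lay nearer the parenchyma than replicate 1. Parenchyma tissue mixed into them would need a like share from both kinds of marker, but 322 parenchyma-high probes needed a median share of 0.132 (quartiles 0.038 to 0.299) and 602 cortex-high probes 0.558 (0.426 to 0.709), a difference of 0.426. Slide is argued against by the gap of 79.72 on component 2 within slide 4, which held all 3. So is parenchyma labelled as replicate 2 or 3: its lowest week 12 array lay 132.83 above the highest cortex array. The highest r of both replicates with either week 8 parenchyma group lay at least 0.04 below the lowest r within it. That replicate 1 is thin root was not tested: the highest r of these 3 with pre-tuberous root, 0.9837, exceeded that among them, 0.9796. A difference between the plants or in where the cortex was taken also stays open as a hypothesis.

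The third pattern is that storage and intermediate parenchyma differed at 3292 probes at week 8 and at 333 at week 12. A larger spread at week 12 is argued against by the ratio of mean SD, 0.795 (0.391 at week 8 and 0.31 at week 12), scaling by the counts, that of week 8 being at least 8.3 times that of week 12 under every other scaling, and arrays exchanged between the groups because splits that exchange 1 array of each called at most 21 probes. With slide as a block, which rests the week 8 difference on the 1 storage array of slide 2, the counts fell to 1912 and 55. The week 8 differences kept a median share of 0.993 (quartiles 0.795 to 1.185, median size 1.69 before and 1.70 after) while their median SE grew from 0.41 to 0.57, so calls ended mostly for lack of precision, which argues against slide as the whole cause. Also open, as a hypothesis found on the same data, is that intermediate parenchyma reaches the state of storage parenchyma between the weeks, which samples taken in between would test.

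For every other comparison the 6 arrays allow 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave the most probes. The real count and the highest other were 11945 against 26 for storage parenchyma against pre-tuberous root at week 8 and 16325 against 4 at week 12, 7576 against 16 and 5070 against 501 for storage cortex, 8330 against 2 and 16615 against 1 for intermediate parenchyma, and 3402 against 31 and 3820 against 15 for intermediate cortex. For parenchyma against cortex they were 9194 against 1215 and 9374 against 12 in storage root and 5404 against 2 and 14446 against 10 in intermediate root. Over time they were 4364 against 74 from fibrous to pre-tuberous root, 8850 against 5 in pre-tuberous root, 9800 against 12 in storage parenchyma, and 1925 against 128 and 45 against 15 in leaves. They were 22330 against 26 for leaves against fibrous root, and 3292 against 333 and 333 against 21 for storage against intermediate parenchyma at weeks 8 and 12.

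Where the numbers pair the samples, the real split is compared with the 4 splits, itself included, that part every pair. The highest of the other 3 gave 10 probes for storage cortex against pre-tuberous root at week 12, 1 for intermediate parenchyma and 31 for intermediate cortex against pre-tuberous root at week 8, 2 for storage parenchyma against cortex and 1 for intermediate parenchyma against cortex at week 8. The other 6 splits keep 2 members of a pair together, and the higher counts of 501 and 1215 came from such splits.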

How the results depend on the processing

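Spike-in scaling, storage cortex by replicate 1 alone, root arrays alone and the list tests under other scalings and blocks were tests chosen only after the result was seen. Over all alternatives, 354 of the counts stayed within 1.5 times their main value and 67 did not, and of the results of the lists fixed beforehand 3069 stayed on their side of the threshold, 59 gained a call, 62 lost it and 0 reversed. Median centring, the deposited table, the compared groups' filter, the trended prior and slide as a random block moved no count past 1.5 times. Unless said otherwise, the cause was not tested.

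Counts follow in this order: against pre-tuberous root at weeks 8 and 12, storage parenchyma, storage cortex, intermediate parenchyma and intermediate cortex; parenchyma against cortex at weeks 8 and 12 in storage and in intermediate root; pre-tuberous against fibrous root; and over time pre-tuberous root, storage parenchyma and leaves. Normexp gave 6448, 9875, 3555, 2334, 3720, 10424, 1538, 2154, 4812, 4658, 2382, 8896, 2296, 4012, 4909, 682 and, from week 8 to 12, 14. No fold threshold, which by construction adds probes, gave 20388, 25495, 14427, 9597, 15458, 25665, 6181, 6782, 16064, 17621, 8909, 23545, 7261, 16636, 18146 and 4511.

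Slide as a fixed block, which leaves few arrays to tell tissue from slide, gave 4671 for storage parenchyma, 827 for storage cortex, 1515 for intermediate parenchyma and 2104 for intermediate cortex against pre-tuberous root at week 8, 2825 for intermediate parenchyma against cortex at week 8, 2576 for pre-tuberous root between weeks and 19 for leaves from week 8 to 12. The arrays of 1 slide alone gave 2095 for intermediate cortex at week 8 and 152 for leaves from week 4 to 8. Where slide and group could not be told apart (7 results) no fixed block was run, and scan day as a block was not run because it follows the slides. An adjusted p under 0.01, a stricter threshold, left 3196 for storage cortex at week 12, 2059 and 2445 for intermediate cortex, 1077 and 17 for leaves and 5564 for the interaction. Spike-in scaling gave 3357 for storage cortex and 2497 for intermediate cortex at week 12, and 7795 and 13 for leaves. The compared arrays alone, with fewer samples behind the spread, gave 2130 for storage cortex at week 12, and 152 and 0 for leaves (limma, 4156 probes at an unadjusted p under 0.05). With 1 probe per gene, fewer were tested and leaves from week 4 to 8 gave 1209. Without a filter the interaction gave 19721 of 59079 probes. Quantile normalization gave 76 for leaves from week 8 to 12, and storage cortex by replicate 1 alone gave 139 at week 12, where 1 array takes its spread from other groups and calls are lost by construction.

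Leaving out 1 array at a time, where the pair left is assumed to vary like the other groups, moved 5 comparisons past 1.5 times: storage cortex at week 12 from 2937 (without its replicate 3) to 6830 (without replicate 1), intermediate cortex from 2116 to 3749 at week 8 and from 2291 to 4251 at week 12, and leaves from 1241 to 1935 and from 19 to 74.

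With the replicate block, counts of all 19 results stayed within 1.5 times. It ended calls of added lists alone: among paired samples, that of class III peroxidases in intermediate parenchyma against cortex at week 8 (adjusted p = 0.0544, 0.00232 to 0.397 over all alternatives, median -0.47), and it changed no other call there. Among samples that share a number alone, no r pattern held, each sample correlated best with its own number in no such comparison, and the block ended the calls of KNOX and BELL (0.0558, median 0.49) and phloem protein 2 (0.0589, median -1.47) for storage parenchyma at week 8.

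Of the lists fixed beforehand, an estimated correlation ended 47 calls, all probes of a list ended 2 and added 14, normexp ended 2 and added 8, quantile normalization ended 2 and added 5, slide as a fixed block ended 7 and added 12, spike-in scaling ended 2 and added 18, and median centring added 2, while of the added lists' 32 calls an estimated correlation left 1. Under normexp the medians of class III peroxidases turned positive at week 12 for storage parenchyma (0.125, from -0.862) and intermediate parenchyma (0.056, from -0.817) against pre-tuberous root and for storage parenchyma against cortex (0.131, from -0.33). Signal over background limits what the arrays show: of 59079 probes, 41512 were well above background in at least 1 group and the others were not tested.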

Other observations

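The lists of this part were added and tested only after the result was seen. In storage cortex of week 8, of the cytokinin response regulators, which relay that signal, 13 of 19 genes rose, 1 fell and 5 did not pass (14 and 1 over the list alone, median 1.26, adjusted p = 7.45e-06, adjusted p = 0.0362 with an estimated correlation). In storage parenchyma of week 8, 11 of 19 genes rose, 1 fell and 7 did not pass (11 and 1 over the list alone, median 0.92, adjusted p = 0.00168, adjusted p = 0.113 with an estimated correlation), and in intermediate cortex 8 of 19 genes rose, 2 fell and 9 did not pass (8 and 2 over the list alone, median 0.77, adjusted p = 0.000911, adjusted p = 0.181 with an estimated correlation). Of the gibberellin oxidases, in storage parenchyma of week 8 0 of 15 genes rose, 9 fell and 6 did not pass (0 and 9 over the list alone, median -1.73, adjusted p = 0.00168, adjusted p = 0.113 with an estimated correlation), and against storage cortex 0 of 15 genes rose, 9 fell and 6 did not pass (0 and 10 over the list alone, median -1.72, adjusted p = 0.00271, adjusted p = 0.112 with an estimated correlation). Of the class III peroxidases, 9 of 71 genes rose, 40 fell and 22 did not pass (9 and 41 over the list alone, median -1.43, adjusted p = 0.000212, adjusted p = 0.113 with an estimated correlation) at week 8 and 11 of 71 genes rose, 28 fell and 32 did not pass (11 and 28 over the list alone, median -0.86, adjusted p = 0.00186, adjusted p = 0.322 with an estimated correlation) at week 12, where normexp turned the median to 0.125 and spike-in scaling ended the call (adjusted p = 0.0549, median -1.71). Against storage cortex, 14 of 71 genes rose, 31 fell and 26 did not pass (14 and 33 over the list alone, median -0.85, adjusted p = 0.00463, adjusted p = 0.2 with an estimated correlation) at week 8.

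In storage parenchyma of week 8, of the KNOX and BELL genes, 9 of 18 genes rose, 2 fell and 7 did not pass (9 and 2 over the list alone, median 0.49, adjusted p = 0.0367, adjusted p = 0.313 with an estimated correlation), and of the phloem protein 2 genes 3 of 16 genes rose, 9 fell and 4 did not pass (3 and 9 over the list alone, median -1.47, adjusted p = 0.0367, adjusted p = 0.15 with an estimated correlation). These calls ended with quantile normalization (adjusted p = 0.0595 and 0.0506, medians 0.46 and -1.28), the latter also with normexp (0.075, median -0.74). Of the suberin enzymes in parenchyma against cortex at week 8, in storage root 0 of 7 genes rose, 4 fell and 3 did not pass (0 and 5 over the list alone, median -1.76, adjusted p = 0.0128, adjusted p = 0.2 with an estimated correlation) and in intermediate root 0 of 7 genes rose, 4 fell and 3 did not pass (0 and 4 over the list alone, median -2.16, adjusted p = 0.00876, adjusted p = 0.397 with an estimated correlation). From fibrous to pre-tuberous root, 0 of 7 genes rose, 5 fell and 2 did not pass (0 and 5 over the list alone, median -2.37, adjusted p = 0.000599, adjusted p = 0.184 with an estimated correlation). Of the cellulose synthase A genes, in storage parenchyma of week 12 against week 8 0 of 9 genes rose, 7 fell and 2 did not pass (0 and 7 over the list alone, median -1.57, adjusted p = 3.08e-05, adjusted p = 0.278 with an estimated correlation), and in the change of the contrast with pre-tuberous root 0 of 9 genes rose, 6 fell and 3 did not pass (0 and 6 over the list alone, median -1.39, adjusted p = 0.0014, adjusted p = 0.315 with an estimated correlation). Among heat shock proteins proper, 14 of 85 genes rose, 38 fell and 33 did not pass (14 and 38 over the list alone, median -0.46, adjusted p = 0.0115, adjusted p = 0.158 with an estimated correlation) in storage parenchyma against pre-tuberous root at week 8 and 22 of 85 genes rose, 43 fell and 20 did not pass (22 and 45 over the list alone, median -0.60, adjusted p = 0.00136, adjusted p = 0.206 with an estimated correlation) at week 12, a call that ended on spike-in scaling (adjusted p = 0.0534, median -1.45). Without phosphofructokinases, of the sucrose genes 7 of 34 genes rose, 12 fell and 15 did not pass (7 and 12 over the list alone, median 0.16 but mean -0.34 and test downward, adjusted p = 0.701) in the same contrast at week 8.

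Further comparisons were counted. Storage parenchyma had 1232 probes higher and 2060 lower than intermediate parenchyma at week 8, and 8 higher and 325 lower at week 12. Storage cortex had 591 higher and 841 lower than intermediate cortex at week 8, and 1185 higher and 948 lower at week 12. Leaves of week 12 had 577 higher and 1018 lower than those of week 4.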
